A study of Mus musculus with 2 samples.

How the data were processed

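DNase-seq libraries were made from nuclei of the left cerebral cortex of 2 female B6CASTF1/J mice aged 10 days. The labels number the libraries as biological replicates 1 and 2 and the animals separately, while both carry the same donor identifier of the strain. They formed 1 group, so no conditions, batches or pairs were compared, and any spread between the libraries joins animal and technical variation.

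The deposited files of each library were 2 peak lists, 1 list of footprints and 1 list of positions with the false discovery rate of their cut rate. Per the file descriptions deposited with each library, all were made from that library's own filtered alignments on the mm10 build, and replicates were not pooled. The aligner, peak caller, footprint caller, their versions and their thresholds were not given in the sources used here. The signal of a peak, as deposited, was 1 value per peak scaled by library; the scale was not given in the sources used here. All signal values of a library were whole multiples of 1 step (100% within 0.01 of a whole number), 0.00692 in replicate 1 and 0.00758 in replicate 2. Differences of signal between the libraries therefore depend on a scaling by the authors that could not be checked, and the ratio was also computed in steps. In the deposited footprint lists, the p-value column held 0.01 throughout, so footprints could not be ranked. The deposited lists of positions gave FDR values under 0.05, over 30.4 Mb in replicate 1 and 34.6 Mb in replicate 2. The p, q and score columns of the peak lists were unfilled and not used.

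The presence of 2 peak lists per library was not foreseen in the plan. The smaller was taken as the main list after the numbers of peaks were seen and before any overlap, gene list or motif result; the larger served as an alternative. Every peak of the smaller list held a position with an FDR of at most 0.001 (highest 0.000992 in replicate 1 and 0.000997 in replicate 2), and the larger lists, of 109563 and 121943 peaks, reached just under 0.05. Depth was read from the signal steps on the assumption of 1 step per cut per M (mega) tags. Intervals on shares were 95% Wilson intervals and cover counting error only. Standard deviations are over n = 2 libraries.

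The reference was GRCm38.p6, the assembly of mm10, with GENCODE M21 genes; chromosome names and lengths were compared before use. B6CASTF1/J mice carry a CAST/EiJ genome copy that differs from this reference, and reads were not assigned to parental alleles here. Peaks were compared by an overlap of at least 1 bp. Chance overlap came from 100 circular shifts within each chromosome, and chance overlap of footprints from 100 random placements within shared peaks. A shared peak is a peak of replicate 1 that overlaps one of replicate 2. Where it overlapped more than 1, its signal was compared with the highest of them. Peaks were assigned by midpoint to a window of 1 kb around any annotated start site, else to exon, intron or between genes. Peaks around a gene were counted in its body extended by 50 kb.

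Fixed before the data were examined were 15 gene lists with 191 genes, of which 14 were tested and 1 checked sex, and 24 motifs. All 191 symbols were found in the annotation. A gene counted when both libraries had a peak within 500 bp of any of its start sites, which need not be the same peak. Its promoter signal was the highest of such peaks, taken in each library on its own. Each list was compared with 10000 random lists of protein-coding genes matched on the decile of promoter CpG observed over expected, with a two-sided permutation p adjusted by Benjamini-Hochberg over the 14 lists, at a threshold of 0.05. Motifs were matched on both strands in footprints extended by 5 bp and in windows of the same lengths placed at random in the peaks outside footprints. Shares were compared by Fisher's exact test in each library with adjustment over the 24 motifs, and a motif was called when it passed in the same direction in both.

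Genes named in the text followed a rule fixed in advance. It took for each list the 2 members with the highest mean promoter signal, and the members with or without a peak where these were at most 3. It also took the 5 genes with the most shared peaks, with ties, the 5 autosomal shared peaks of highest mean signal, the 5 genes with the most peaks of 1 library, with ties, and the genes of the sex check. Other names picked for their values were chosen after these were seen and are marked as such. Some genes that the rule takes are not reported here. Alternatives planned in advance were a reciprocal overlap of 50%, the stronger 50% of peaks, equal numbers of top peaks, the larger lists, linear signal, other windows, random lists not matched on CpG, other footprint extensions, control windows 30 bp from the footprint, and each library alone. Added after the data were examined were 5 more: the stricter list against the other library's larger list, the gene's own start only, matching on CpG content and number of start sites, footprints inside the stricter peaks, and shuffled consensus sequences (5 per motif).

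The steps were tested on simulated data. Overlap counts equalled those of bedtools (42227 of 60071 simulated peaks). Of 400 unchanged lists, 1% were called at p under 0.05, and of 400 lists raised to a share of 98%, 99.75% were. A motif planted in 1000 of 50000 windows was found in 1027, and 0 other motifs were called. Simulated windows and controls had the same base composition, unlike footprints and their control windows, so false calls from a difference in GC content were not covered. For counts of distal peaks, 7.5% of 200 unchanged lists were called against 5% nominal, and 89% of 200 lists with tripled counts. Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, matplotlib 3.10.9, bedtools 2.31.1 and, for near-identical copies, BLAST 2.17.0. A copy was a match of at least 95% identity over at least 80% of the peak.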

Results

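Open chromatin was mapped by DNase-seq in the left cerebral cortex of 2 female mice aged 10 days. The animals were B6CASTF1/J, the first-generation cross of the C57BL/6J laboratory strain with CAST/EiJ, a wild-derived strain. DNase I cuts DNA that is not wrapped in closed chromatin, so clusters of cuts mark promoters, enhancers and other accessible regions, and short protected stretches inside them are called footprints. The libraries formed 1 group with 2 biological replicates, and the labels gave no treatment or second tissue. The comparisons were therefore between the replicates, and between genomic regions, gene groups and sequence motifs within them. All coordinates are on mm10, counted from 1.

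In cortex chromatin, the stricter of the 2 deposited peak lists held 60071 peaks covering 11.4 Mb in replicate 1 and 70563 peaks covering 13.2 Mb in replicate 2. Peaks were narrow, with a median width of 193 bp in replicate 1 and 191 bp in replicate 2. The median peak signal was 0.830 and 0.925, respectively. Every signal value was a whole multiple of a step, 0.00692 in replicate 1 and 0.00758 in replicate 2. If the step stands for 1 cut per M (mega) tags, which the files do not state, the libraries held 145 M and 132 M tags. The median peak then rested on 120 cuts in replicate 1 and 122 in replicate 2, with counting errors of 9.13% and 9.05%. These errors leave out any other spread between the libraries.

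Most accessible regions of the cortex were found in both animals. Of the peaks of replicate 1, 50856 overlapped a peak of replicate 2 (84.7%, 95% Wilson interval 84.4 to 84.9), and of those of replicate 2, 50852 overlapped one of replicate 1 (72.1%, 71.7 to 72.4). The shared sequence was 8.81 Mb of a union of 15.8 Mb, a Jaccard index of 0.557. In 100 circular shifts of the peaks along their chromosomes, the overlap for replicate 1 averaged 1.03% and reached 1.14%. Peaks found in 1 library were weaker than shared peaks: the 9215 of replicate 1 had a median of 74 signal steps against 134, and the 19711 of replicate 2 had 79 against 157. Of these, 64.5% in replicate 1 and 66.7% in replicate 2 lay in the larger peak list of the other animal, a comparison added after the data were examined. The intervals cover counting error only.

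Strong regions in one animal were strong in the other. Across the 50856 shared peaks, log2 signal had a Pearson correlation of 0.953 and a Spearman correlation of 0.934; these are across peaks, which are not independent replicates. Signal was higher in replicate 2 at 43168 of them (84.9%), by a median log2 of 0.37 (1.29-fold, SD 0.35), or 0.24 when counted in steps. Signal differed by over 2-fold at 1328 peaks with replicate 2 higher and at 24 with replicate 1 higher. Each peak of replicate 1 was set against the highest overlapping peak of replicate 2, a rule that favours replicate 2. At a reciprocal overlap of 50%, the counts were 1000 and 14 of 44101 pairs, and the median log2 stayed at 0.37. The widest gap toward replicate 2 was at the promoter of Acvr1b (chromosome 15, 101174041 to 101174104), an activin receptor, with a signal of 0.886 in replicate 1 and 3.03 in replicate 2. The widest gap toward replicate 1 was at a peak between genes near the chemokine gene Ccl9 (chromosome 11, 83556421 to 83556660), with 1.57 and 0.584. Acvr1b and Ccl9 were chosen after their values were seen.

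**Figure D1:**
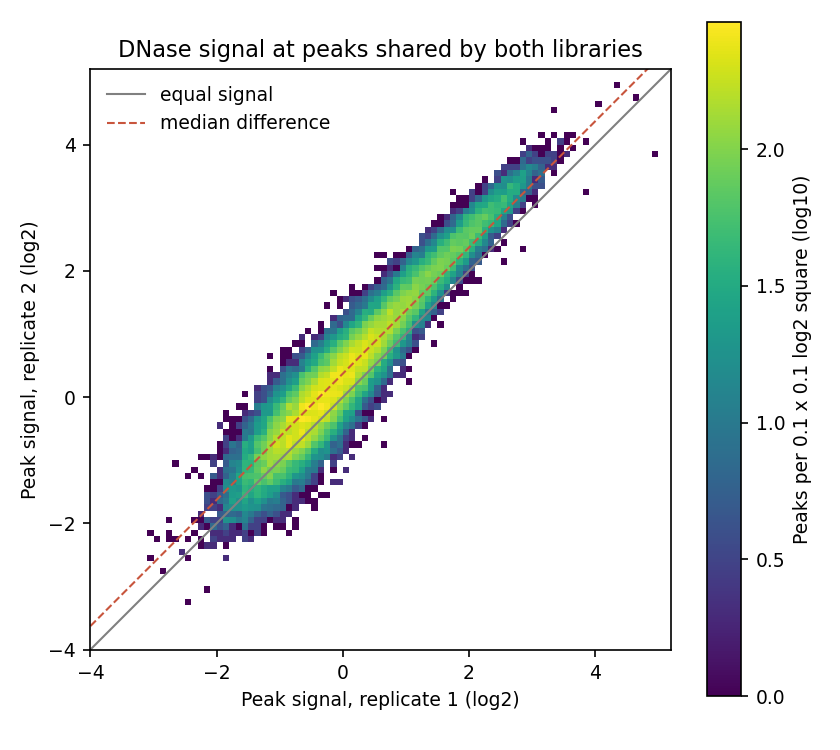
Signal of each of 50856 shared peaks in replicate 1 (x axis, log2) and replicate 2 (y axis, log2), counted in squares and coloured by the log10 number of peaks. The solid line marks equal signal and the dashed line the median log2 difference of 0.37; most peaks lie above the solid line.

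Accessible chromatin was concentrated at the starts of genes. Of the shared peaks, 18900 had their midpoint within 1 kb of an annotated transcription start site (37.2%, Wilson interval 36.7 to 37.6), where 6.05% of the genome lies, a 6.14-fold excess. Introns held 29.0% of the shared peaks against 38.4% of the genome, regions between genes 30.6% against 52.3%, and exons 3.23% against 3.18%. Promoter regions were less frequent among peaks of 1 library, at 28.5% of those of replicate 1 and 26.0% of those of replicate 2. With a window of 2 kb the excess at start sites was 3.84-fold, and with 500 bp it was 9.87-fold.

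Chromosome X was sparsely covered and chromosome Y nearly empty in these female animals. The autosomes together held 20.7 shared peaks per Mb, from 16.7 on chromosome 3 to 29.4 on chromosome 11. Chromosome X held 7.71 per Mb, so that the autosomes were 2.68-fold denser, and chromosome Y 0.0567. The promoter of Xist, whose RNA coats the inactive X chromosome of females, was open in both libraries (chromosome X, 103460366 to 103483254, signal 1.06 ± 0.12, SD, n = 2). None of the 4 Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y had a promoter peak in either list of either library. Their X-linked counterparts all did in both: Kdm6a, a histone demethylase (chromosome X, 18162575 to 18279936), had 13.9 ± 3.86 (SD, n = 2). Ranked by the lower signal of the 2 libraries, 11.2 for Kdm6a, it stood above 99.95% of all promoters with a peak. Kdm5c followed with 8.20 ± 3.01, Ddx3x with 3.89 ± 1.01 and Eif2s3x with 2.82 ± 0.29.

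The 5 strongest shared autosomal peaks lay at very different kinds of sites. They are named by the gene with the nearest start site, and an exon holding a peak may belong to another annotated gene. The highest was on chromosome 15 (99735661 to 99736060), in an exon 10243 bp from the start of Cox14, a factor for assembling cytochrome oxidase, with 24.7 in replicate 1 and 27.3 in replicate 2. A peak at the start of Gm42418, a long noncoding RNA gene (chromosome 17, 39846781 to 39846920), had 19.7 and 30.1 and is uncertain, since 1 near-identical copy of the sequence lies on another chromosome (99.3% identity). The promoter of Hjurp, a chaperone of the centromeric histone (chromosome 1, 88277521 to 88277760), had 16.6 and 24.8. That of Dynlt1b, a dynein light chain gene (chromosome 17, 6430001 to 6430180), had 9.91 and 22.7 and is likewise uncertain, with 3 other near-identical copies on the same chromosome. An exonic peak 3934 bp from the start of Ubqln1, a ubiquitin-binding protein (chromosome 13, 58177581 to 58177800), had 14.2 and 16.5.

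Peaks were also counted around each protein-coding gene, in its body extended by 50 kb. The median gene had 5 shared peaks. Gm20388 on chromosome 8 (119910841 to 124345722) had 200 and Fgfr2, a fibroblast growth factor receptor on chromosome 7 (130162451 to 133123350), had 86, but their annotated models span 4435 and 2961 kb. Next came 4 genes with 37 each: Gm37240, the transcription activator Camta1, the acid-sensing channel Asic2, and Kalrn, a guanine nucleotide exchange factor of dendritic spines. Around Kalrn (chromosome 16, 33969073 to 34573532) this was 5.25 peaks per 100 kb, against a median of 3.25 over genes. Gm20388 and Fgfr2 also led both counts of peaks found in 1 library. Among shorter genes, Igsf8 (chromosome 1, 172261641 to 172319841) and the nearby potassium channel gene Kcnj9 had 23 and 22 peaks of replicate 1 alone. Ttyh1 (chromosome 7, 4119408 to 4136708) and its neighbours Leng8, Leng9 and Cdc42ep5 had 25 each of replicate 2 alone. The windows of such neighbouring genes overlap, so their counts share peaks and are not separate results.

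Gene lists fixed before the data were examined were then compared by promoter. Of 21938 protein-coding genes, 12105 (55.2%) had a peak within 500 bp of a start site in both libraries, with a median signal of 2.89. The share was 91.9% in the highest decile of promoter CpG content and 5.24% in the lowest, so each list was set against 10000 random lists matched on CpG content. Of the 14 lists tested, 1 had more promoter peaks than its random lists and 4 had fewer, by a two-sided permutation test with Benjamini-Hochberg adjustment. The smallest p these lists can give is 0.0002, before adjustment. Genes are not replicates, so the tests describe these libraries.

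Promoters of general neuronal genes were open more often than matched promoters. Of 14 pan-neuronal genes, 13 had a promoter peak in both animals, against a random mean of 8.07 (permutation, adjusted p = 0.00560). Syt1, the calcium sensor of synaptic vesicles (chromosome 10, 108497650 to 109010982), had the highest signal at 3.75 ± 1.21 (SD, n = 2), and Dlg4, the postsynaptic scaffold PSD-95 (chromosome 11, 70016942 to 70047522), had 3.47 ± 0.89. Rbfox3, which encodes the neuronal nuclear antigen NeuN, was the exception, with a peak of 1.29 in replicate 2 and none in the stricter list of replicate 1. In the larger lists its promoter had 0.920 and 1.29. With random lists also matched on the number of start sites, an alternative added after the data were examined, the adjusted p was 0.0650 and no list was called higher.

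Genes of the main cortical neuron classes did not pass the test against matched promoters. Of 18 cortical excitatory neuron genes, 11 had a promoter peak in both libraries against a random mean of 11.1 (adjusted permutation p = 1). Camk2a, a synaptic kinase, had 2.92 ± 0.62 (SD, n = 2) and Lhx2, a regulator of cortical identity, had 2.74 ± 0.85. Fezf2 and Slc17a7 had no promoter peak in either stricter list, but in the larger lists Slc17a7 had 0.733 in replicate 1 and 0.993 in replicate 2, and Fezf2 0.561 in replicate 2 alone. Of 16 cortical interneuron genes, 7 had one against 10.7 (adjusted permutation p = 0.106). Adarb2 had 1.49 ± 0.34 and Sox6 had 1.38 ± 0.10 (SD, n = 2), while the GABA synthesis genes Gad1 and Gad2, the transporter gene Slc32a1 and the neuropeptide genes Sst, Npy and Vip had none in either stricter list. The larger list of replicate 2, but not that of replicate 1, held promoter peaks of Gad2 (0.637), Slc32a1 (0.576) and Npy (0.379). These genes without a peak in the stricter lists were picked out after their values were seen. The interneuron list was called lower without replicate 1 (permutation, adjusted p = 0.0275) and, in an added alternative, with only the gene's own start (4 genes, adjusted p = 0.00840).

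Among glia, vascular and immune cells, only the vascular list was called. Of 12 endothelial and mural genes, 2 had a promoter peak in both libraries against a random mean of 6.63 (permutation, adjusted p = 0.00896): Foxc1, with 0.788 ± 0.20 (SD, n = 2), and the pericyte gene Rgs5, with 0.615 ± 0.009. Astrocyte genes had 7 of 12 against 6.78 (adjusted permutation p = 1), led by Glul, glutamine synthetase, at 4.92 ± 0.77 and Sox9 at 2.74 ± 0.03 (SD, n = 2). Oligodendrocyte lineage genes had 4 of 12 against 5.87 (adjusted permutation p = 0.383), led by Olig1 at 1.67 ± 0.58 and Pdgfra, the receptor of their progenitors, at 1.45 ± 0.41. Microglia genes had 3 of 12 against 3.18 (adjusted permutation p = 1), including the complement genes C1qb at 0.603 ± 0.02 and C1qa at 0.583 ± 0.03 (SD, n = 2). The vascular call was lost in the larger peak lists, where 4 genes had a peak (permutation, adjusted p = 0.0620), and without replicate 2, where 3 did (adjusted p = 0.0526). Astrocyte genes had 11 of 12 against 7.54 in the larger lists, still with no call (permutation, adjusted p = 0.0595).

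Regulators of other brain regions had the largest deficit of the 14 lists. None of 16 genes such as the hindbrain and spinal cord Hox genes, En1 and Otx2 had a promoter peak in the stricter list of either library, against a random mean of 12.7 (permutation, adjusted p = 0.00280). Muscle genes had 0 of 12 against 4.95 (permutation, adjusted p = 0.00560). Pluripotency and germ line genes had 1 of 12 against 6.14 (permutation, adjusted p = 0.00700), which was Dazl, a germ cell RNA-binding protein, at 1.21 ± 0.22 (SD, n = 2). The muscle call was lost with a 2 kb window, where 3 genes had a peak (permutation, adjusted p = 0.243), and in the larger lists, where 2 did (adjusted p = 0.0610). Liver genes had 1 of 12 against 3.29 (adjusted permutation p = 0.266), which was Apoh. Its highest signal at any start site was 2.67 in replicate 1 and 0.652 in replicate 2. No shared peak had so wide a gap toward replicate 1, so these values belong to different peaks. Red blood cell genes had 1 of 10 against 1.78 (adjusted permutation p = 1).

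Every activity-regulated and housekeeping gene had an open start site, though neither list passed the test against lists of like CpG content. All 12 activity-regulated genes, which neurons switch on after firing, had a promoter peak in both libraries against a random mean of 9.13 (adjusted permutation p = 0.106). The early growth response gene Egr1 had 5.41 ± 1.74 and the synaptic scaffold gene Homer1 had 5.07 ± 0.30 (SD, n = 2). All 12 housekeeping genes had one against 9.53 (adjusted permutation p = 0.144), with Rpl13a at 8.33 ± 2.17 and Hsp90ab1 at 6.96 ± 2.52 (SD, n = 2). Without matching on CpG content, both lists were called higher by the permutation test, with adjusted p = 0.00653 and 0.00373, and the red blood cell and liver lists lower, with 0.0192 and 0.00653. Housekeeping genes were also called higher among the stronger 50% of peaks (permutation, adjusted p = 0.0439). With only the gene's own start, an added alternative, the activity-regulated list turned from above to below its random mean, at 8 of 12 against 8.62 (permutation, adjusted p = 0.958), and housekeeping genes had 10 of 12 against 9.08 (permutation, adjusted p = 0.928).

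**Figure D2:**
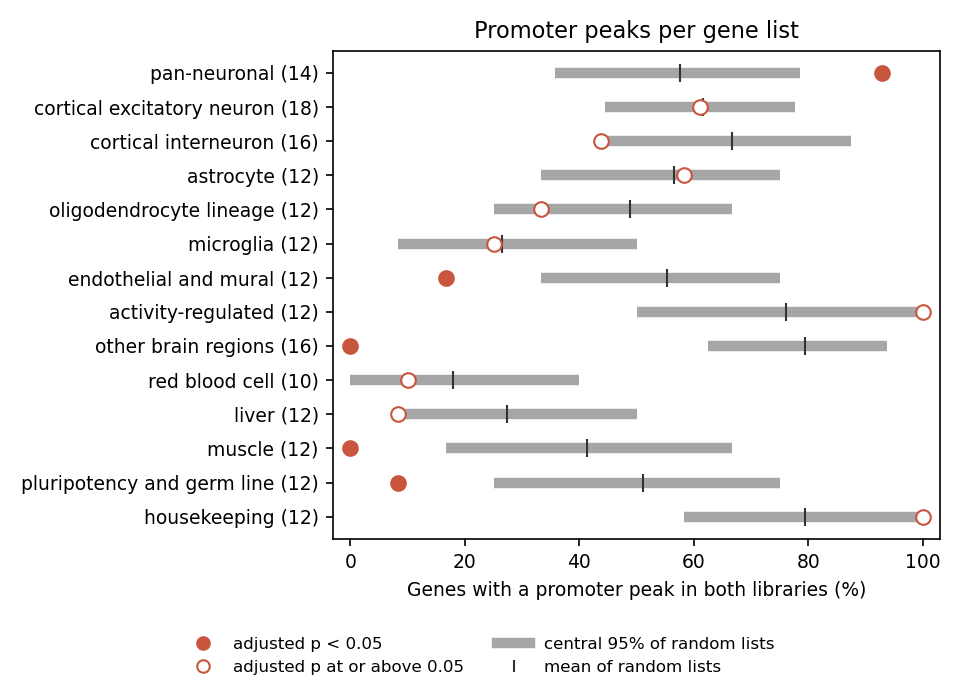
Share of each gene list with a promoter peak in both libraries (points, %), with the number of genes in parentheses. Grey bars span the central 95% of 10000 random lists matched on CpG content and ticks mark their mean; pan-neuronal genes (92.9%) lie above their bar, and vascular, other brain region, muscle and germ line genes (16.7%, 0%, 0% and 8.33%) below theirs.

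Fewer than 50% of all footprints were found in both animals, but more than 50% of those of replicate 1 in shared peaks. Replicate 1 had 212785 footprints and replicate 2 had 224029, with a median width of 9 bp in each. Of the stricter peaks, 88.1% in replicate 1 and 86.5% in replicate 2 held a footprint. In all, 46.1% of the footprints of replicate 1 (Wilson interval 45.9 to 46.3) and 45.6% of those of replicate 2 (45.4 to 45.8) overlapped one of the other library. Within shared peaks, 58.6% of the footprints of replicate 1 did, against 35.1% after moving them at random within these peaks, 1.67 times as many. Requiring a reciprocal overlap of 50% gave 42.1% against 12.3%, 3.41 times as many.

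Footprints held matches to consensus sequences of architectural, promoter and neural factors, but binding itself was not tested. Of 24 consensus motifs fixed in advance, 11 were more frequent in footprints than in windows of the same lengths elsewhere in the peaks, in both libraries. CTCF, which anchors chromatin loops (CCASYAGRKGGC), was found in 4266 footprints of replicate 1 and 3953 of replicate 2, a ratio to control windows of 59.3 (95% interval 46.9 to 74.8) and 36.9 (30.5 to 44.8). The nuclear factor I palindrome, of factors that act in glia and maturing neurons, had ratios of 27.0 and 54.0, resting on 3 and 1 control windows. Ratios depended on how far footprints were extended and on the control windows: the mean for CTCF was 48.1 with 5 bp, 125 with 0 bp, 24.9 with 10 bp and 123 with control windows next to the footprint. For nuclear factor I it was 40.5 with 5 bp and 11.5 with 10 bp. Adjusted p-values of these tests come from sites, not replicates. They were 2.71e-20 and 8.26e-15 for nuclear factor I by Fisher's exact test and too small to be represented for CTCF.

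Motifs found mostly near start sites were also enriched. NRF1 had ratios of 47.6 and 9.40, and the cyclic AMP response element CRE of 13.8 and 12.3. SP/KLF had 5.79 and 6.92, EGR 5.28 and 4.57, ETS 2.30 and 2.20, and NFY 1.45 and 1.76. RFX, which lay near start sites less often than footprints in general, had 21.4 and 9.67. With footprints extended by 0 bp the mean ratio was 43.1 for NRF1, 34.7 for RFX, 28.9 for CRE, 15.4 for SP/KLF, 11.3 for EGR and 4.12 for ETS, and with 10 bp it was 16.2 for NRF1, 9.11 for RFX, 8.17 for CRE and 4.23 for SP/KLF. Control windows next to the footprint gave means of 8.40 for EGR and 23.8 for RFX, against 4.92 and 15.5. The mean for NRF1 was 179 with footprints inside the stricter peaks, against 28.5. Of all footprints only 381 in replicate 1 and 282 in replicate 2 held this motif. A mean of 179 thus rests on very few matching control windows in at least 1 library, and its size is uncertain. The proneural E-box CAGATGG, bound by NEUROD and related neuronal factors, was in 3461 and 3330 footprints, with ratios of 2.33 (2.20 to 2.48) and 2.09 (1.97 to 2.22). Its relative, the E-box CAGCTG, had 1.14 and 1.27, a call lost with footprints extended by 0 bp (1.16) or 10 bp (1.02) and with footprints inside the stricter peaks (1.14). Footprints were richer in G and C than control windows, at 57.8% against 53.5% in replicate 1 and 59.2% against 53.4% in replicate 2. Divided by the ratios of shuffled versions of each consensus, an alternative added after the data were examined, the mean ratio was 1.93 for SP/KLF, 1.67 for EGR, 36.9 for CTCF and 2.23 for the proneural E-box. For NRF1 it depended on the library, at 27.0 in replicate 1 and 4.84 in replicate 2.

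For 5 motifs, footprints held fewer matches than control windows. All 5 lack CpG in their consensus, but so do CTCF and the proneural E-box, which were called higher. The 5 were SOX with ratios of 0.69 and 0.70, homeobox TAATTA with 0.61 and 0.43, POU with 0.78 and 0.65, T-box with 0.58 and 0.65, and GATA, of blood regulators, with 0.55 and 0.50. With footprints extended by 0 bp the mean ratios of these 5 lay lower, from 0.163 for GATA to 0.395 for T-box. Set against shuffled versions of the same letters, the direction turned for SOX (1.34), POU (1.70) and GATA (1.13), while homeobox TAATTA (0.87) and T-box (0.96) stayed below 1. POU was not called with footprints extended by 10 bp (0.84) or with control windows next to the footprint (0.83), nor T-box with the latter (0.68). Of the remaining 8 motifs none was called: AP-1, MEF2, ROR, PU.1, HNF4, REST, HNF1 and the TP63-type motif. AP-1 was called lower in 4 alternatives, with footprints extended by 0 bp (0.657) or 10 bp (0.842), inside the stricter peaks (0.676) and without replicate 2 (0.806). Relative to shuffled versions it stood near 1, at 1.03 (0.919 in replicate 1 and 1.14 in replicate 2). MEF2 had no stable direction: it was called lower with 0 bp (0.356) and without replicate 1 (0.556), but its mean ratio was above 1 with 10 bp (1.28), with control windows next to the footprint (1.16) and relative to shuffled versions (1.80). REST, the repressor of neuronal genes outside neurons, matched 9 footprints in replicate 1, with no control window, and 1 in replicate 2, with 1 control window, and was called higher without replicate 2 (adjusted p = 0.00586 by Fisher's exact test). With footprints extended by 10 bp it matched 17 against 1 in replicate 1 (ratio 17, 95% interval 2.26 to 128) and 7 against 1 in replicate 2 (ratio 7, 0.861 to 56.9), still with no call in both.

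**Figure D3:**
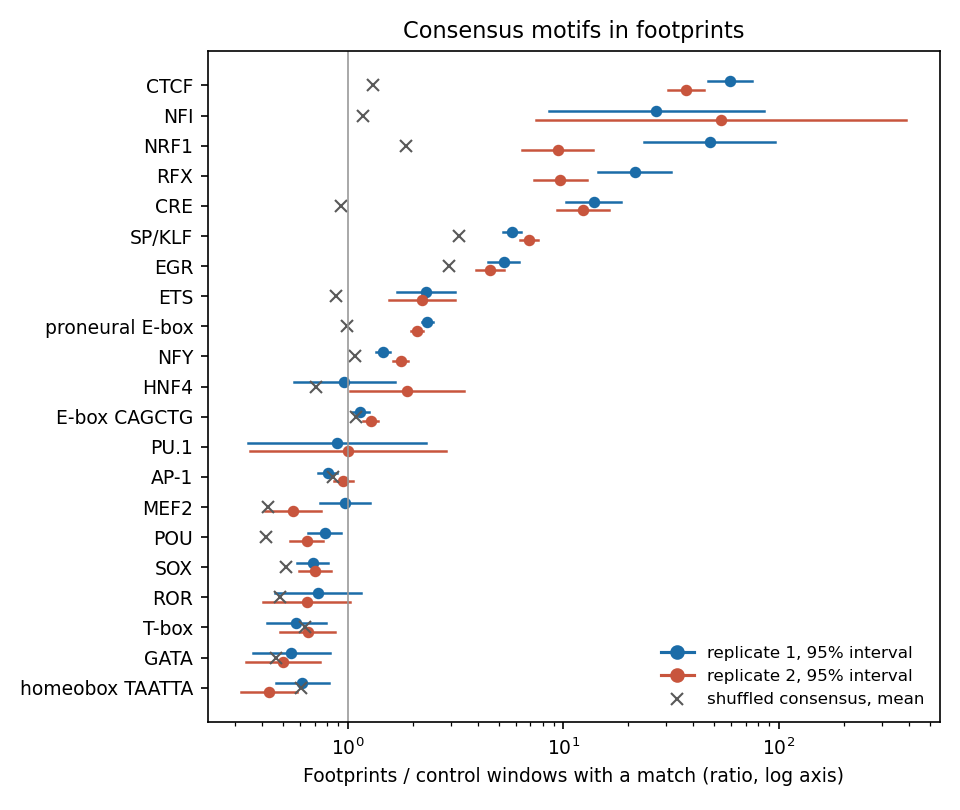
Ratio of the share of footprints with a match to the share of control windows with one (log axis), per motif and library, with 95% intervals. Crosses mark the mean ratio of shuffled versions of the consensus; CTCF (59.3 and 36.9) lies far to the right of its cross, SP/KLF (5.79 and 6.92) less so, and SOX, POU and GATA lie right of theirs while below 1.

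The motifs divided into those at promoters and those away from them. Within 1 kb of a start site lay 39.7% of all footprints of replicate 1 and 39.0% of those of replicate 2. For SP/KLF it was 91.3% (Wilson interval 90.2 to 92.3) and 90.6% (89.6 to 91.5), for ETS 90.8% and 92.8%, for EGR 86.9% and 84.9%, for NRF1 85.3% and 84.8%, for CRE 78.5% and 79.0%, and for NFY 71.0% and 73.2%. For CTCF it was 12.1% (11.2 to 13.1) and 12.5% (11.5 to 13.6), and for the proneural E-box 12.6% (11.6 to 13.8) and 13.2% (12.1 to 14.4). RFX lay below all footprints too, at 26.6% and 27.6%, as did the E-box CAGCTG, at 26.3% and 24.9%. These shares were computed after the motif results were seen.

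**Figure D4:**
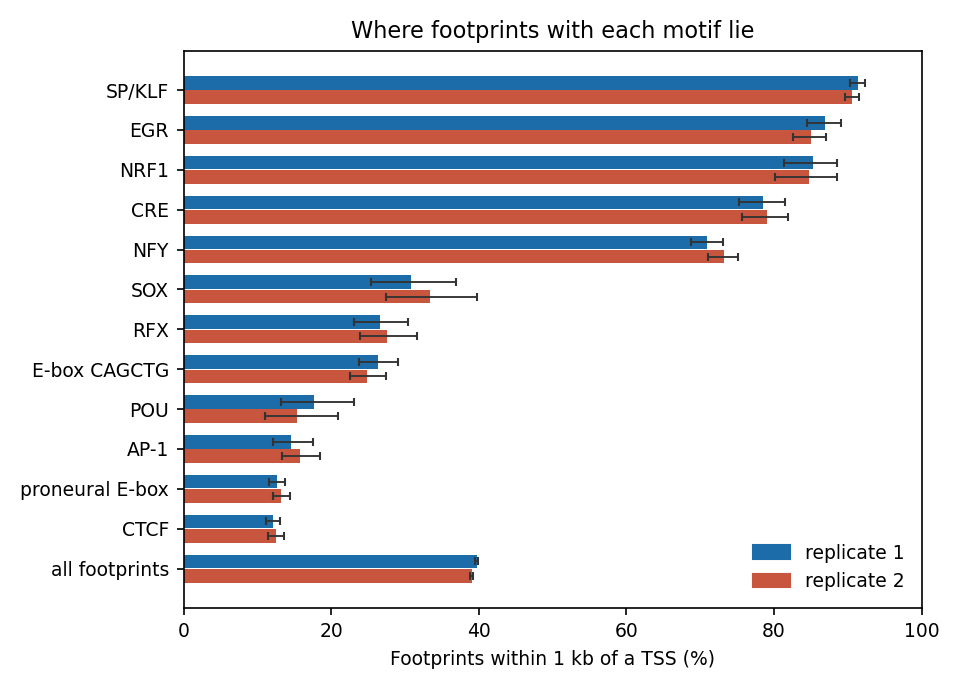
Share of footprints with each motif that lie within 1 kb of a start site (x axis, %), per library, with 95% Wilson intervals; motifs with at least 200 footprints in both libraries are drawn. SP/KLF stands at 91.3% and 90.6% and CTCF at 12.1% and 12.5%, on either side of all footprints at 39.7% and 39.0%.

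The higher signal of replicate 2 was uneven across regions. At promoter peaks the median log2 difference was 0.50 (1.41-fold, higher in replicate 2 at 93.2% of 18900 peaks) and at other peaks 0.29 (1.22-fold, 31956 peaks). It rose from 0.16 in the lowest decile of peak GC content to 0.64 in the highest, and from 0.09 in the lowest decile of mean signal to 0.59 in the highest. The gap between promoter and other peaks was 0.21 on the log2 scale (SE 0.004 over 20 chromosomes, above 0 in all 20), a comparison added after the data were examined. Both libraries belong to 1 group, so this is a difference between animals or libraries, not between conditions.

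**Figure D5:**
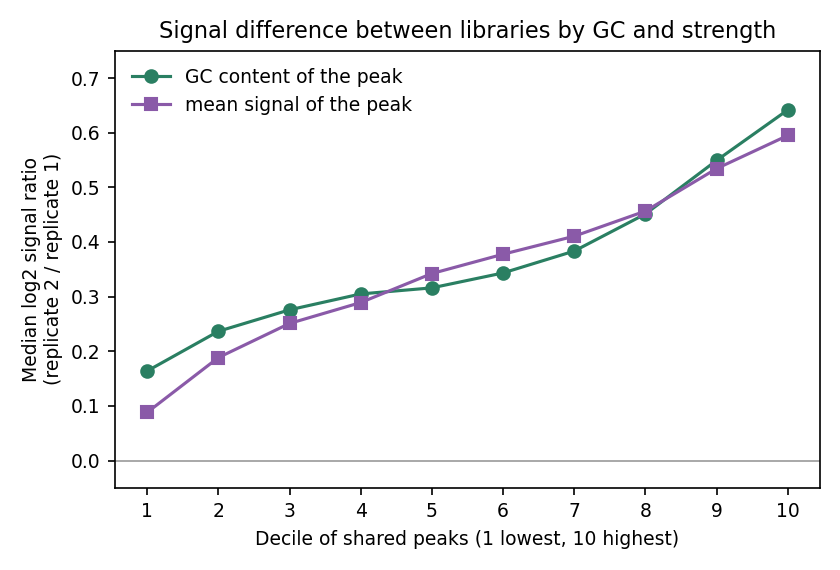
Median log2 ratio of signal, replicate 2 over replicate 1 (y axis), in deciles of the shared peaks by GC content (circles) and by mean signal (squares). Both series lie above 0 throughout, from 0.16 to 0.64 for GC content and from 0.09 to 0.59 for mean signal.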

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

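The test of a male or mixed sample and the counting of overlapping peaks as 1 site were chosen only after the result was seen; the others of this part were fixed before.

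Chromosome Y, which female animals lack, held 7 peaks of the stricter list in replicate 1 and 9 in replicate 2, of which 5 of replicate 1 were among the 50856 shared peaks. The highest lay at 90744581 to 90744820 in replicate 2, with a signal of 4.77. A male or mixed sample would open the promoters of Ddx3y, Uty, Kdm5d and Eif2s3y, and 0 of these 4 had a peak in any list of either library, while 4 of 4 X-linked counterparts had one. The 16 peaks lie at 11 distinct sites, 5 of them found in both libraries. Of the 11 sites, 9 (81.8%, Wilson interval 52.3 to 94.9) have a near-identical copy outside chromosome Y, against 25 of 100 random chromosome Y windows (25%, 17.5 to 34.3), so the peaks may come from reads of such copies, and the general abundance of copies on chromosome Y alone falls short of their share. The remaining 2 sites have copies on chromosome Y only, in the sequence searched, and stay unaccounted for, and no biological explanation was tested. The search covered the assembled chromosomes of the reference, without unplaced or CAST/EiJ sequence.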

How the results depend on the processing

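The comparison with the other library's larger list, the gene's own start, matching on the number of start sites, footprints inside the stricter peaks and shuffled consensus sequences were tests chosen only after the result was seen. Of the values for gene lists under alternatives, 100 kept their side of the threshold, 7 passed it anew and 5 lost it. Of those for motifs with a mean ratio in the main setting, 112 kept their call, 6 gained one and 6 lost it. REST had no such ratio and is outside these counts, although it was called higher without replicate 2. Of the ratios to shuffled consensus, which have no test, 12 kept their side of 1 and 3 turned. Of the summary values, 31 stayed and 42 moved. The stronger footprints were not tried because no value ranks footprints, leaving out a library gives no overlap or agreement, and no shuffled value was had for RFX in replicate 1. No paired analysis was possible because the libraries form 1 group. Unless the construction shows it, as with list size, window and matching, the cause was not tested.

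The stronger 50% of peaks gave 29789 and 35250 peaks, overlaps of 92.3% and 78.1%, a Jaccard index of 0.628, shares of 51.6% near start sites, 2.95% in exons, 22.5% in introns and 23.0% between genes, and 2 lists called higher. The larger lists gave 109563 and 121943 peaks, overlaps of 79.1% and 71.0%, a Jaccard index of 0.514 and 2 lists called lower. Equal numbers of top peaks gave overlaps of 78.3% and 78.2%, the stricter list against the other library's larger list 94.3% and 90.5%, and a reciprocal overlap of 50% gave 73.4% and 62.5% for peaks and 32.9% and 31.2% for footprints. A 2 kb window gave 42.5% near start sites, 2.41% in exons, 26.1% in introns and 29.0% between genes, and a 500 bp window 32.1%, 4.18%, 31.7% and 31.9%. Without either replicate the shares were 34.03% to 35.8%, 3.25% to 3.54%, 29.7% to 30.8% and 31.2% to 31.6%. Random lists not matched on CpG gave 3 lists called higher, and matching on CpG and number of start sites gave 0. Control windows next to the footprint gave 3 motifs called lower. Relative to shuffled consensus, SOX (1.34), POU (1.70) and GATA (1.13) turned from below 1 to above it.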

Other observations

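The tests chosen only after the result was seen were those of sequencing depth, of GC content and strength together, of chance placement and of lower signal in the runs, the neighbour matching of distal peaks, the 50 classes of GC content and of signal, the adjustment of the gap over gene lists, the comparison of single bins, and the bin size and minimum of the runs.

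Open regions away from promoters gathered around activity-regulated genes and, to a like degree, around housekeeping genes. Within 50 kb of the 12 activity-regulated genes lay 42 shared distal peaks, against 20.9 in random lists matched on gene length (2.01-fold, permutation, adjusted p = 0.0224). Every one of the 12 had at least 1, with 7 at Egr1, 6 at Junb, 6 at Fosb and 5 at Fos, all genes of immediate early transcription factors; peaks were not assigned to single genes of a window. The 12 housekeeping genes also had 42, against 20.4 (2.06-fold, permutation, adjusted p = 0.0224), with 7 at the actin gene Actb. With random lists matched on length and on the number of genes starting in the window, the ratios were 2.05 and 2.09 (permutation, adjusted p = 0.0238 and 0.0196). Neither set of random lists was matched on having a promoter peak, which all 12 genes of each list had. Whether the excess is particular to these genes thus stays open. Junb, Fosb, Fos and Actb were chosen after their counts were seen.

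Glial genes had many distal peaks too, but did not pass the test over 14 lists. Astrocyte genes had 54 against 28.8 (1.88-fold, permutation, adjusted p = 0.0896), with 11 around Aldh1l1, 8 around Id3 and 7 around the glutamate transporter gene Slc1a2. Oligodendrocyte lineage genes had 44 against 25.6 (1.72-fold, permutation, adjusted p = 0.123), with 9 around the myelin gene Mbp. Aldh1l1, Id3, Slc1a2 and Mbp were chosen after their counts were seen. That cortical excitatory neuron genes would hold more distal peaks than genes of like length was a hypothesis set before: they had 68, 1.24-fold the random mean of 54.9, at percentile 85.7 (permutation, adjusted p = 0.501), which leaves it open. The remaining 9 lists had adjusted p of 0.394 or more.

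Signal was higher in replicate 2 by a median log2 of 0.37, and by 0.21 more at promoters than at other peaks. Deeper sequencing of replicate 2 would give it the smaller signal step, but its step was 1.10 times that of replicate 1, which argues against depth if a step is 1 cut at a common scale. The promoter gap was 0.0773 (SE 0.008 over chromosomes) within deciles of GC content and 0.0884 (SE 0.005) within deciles of signal, above 0 on 20 of 20 chromosomes, and 0.0758 and 0.0815 with 50 classes in place of deciles. Each property thus removed over 50% of the gap and left 37.2% and 42.6% of it. The bound set in advance against either alone as the whole cause, over 75% left, was not met. It was lowered to 25% after the gaps were seen, so whether either alone is the whole cause stays open. Within joint deciles the gap was 0.0136 (SE 0.008, above 0 on 11 of 20), so a bias by GC content and strength together may account for it. A difference between the animals was not tested.

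No gene group passed the test for an unequal difference between the libraries. Around activity-regulated genes distal peaks had a median log2 of 0.55, at percentile 99.74 of random lists (permutation, adjusted p = 0.0756 over 14 lists). Around genes of other brain regions it was 0.19, at percentile 2.31 (permutation, adjusted p = 0.325). Set against peaks of like GC content and strength, these lists lay at percentiles 87.22 and 12.54. A difference in cell makeup between the samples would move marker lists apart, and 0 of 7 cell type lists lay outside the central 95%. That was set in advance as evidence against it, wrongly, since random lists are widely spread, from 0.19 to 0.48 for lists like the pan-neuronal one, so smaller shifts in cell makeup stay open.

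Peaks found in 1 library lay in runs. The fullest 50 kb bin held 21 of replicate 1 (chromosome 1, 172300001 to 172350000, at Igsf8 and Kcnj9) and 22 of replicate 2 (chromosome 7, 4100001 to 4150000, at Ttyh1, Leng8 and Leng9), beyond the 15 and 17 reached in 1000 reassignments among each library's peaks, which argues against chance placement. In the 7 and 12 bins with at least 10 such peaks, 27.8% and 12.7% lay in the other library's larger list, against 64.9% and 67.1% elsewhere. Each of the bins lay below the share elsewhere. Signal there may be absent from the other library, but the shares were not matched on signal, so a signal under its threshold stays possible. The median signal of these peaks was also lower, 0.453 and 0.417 against 0.512 and 0.599 elsewhere. It lay below the 2.5% bound of random draws (0.470 and 0.546), a bound set after the medians were seen. Single bins went both ways, with 3 of 7 and 7 of 12 below random draws of their size, 0 and 2 above them (1.03 and 0.974), and the fullest bin of replicate 1 at 0.553, so lower signal as a cause stays open, and a difference between animals or parental alleles was not tested.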
